A study of Homo sapiens with 8 samples.

How the data were processed

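Total RNA of SW480 cells, an established human colorectal cancer line, was sequenced on an Illumina instrument after ribosomal RNA removal, per the labels' protocols. The cells had been transfected with small interfering RNA (siRNA) by a lipid reagent, and RNA was purified on columns with DNase digestion. The labels give 4 groups of 2 libraries each, 8 in all: a negative-control siRNA at 0 h and an siRNA against TCF7L2 at 24, 48 and 72 h. The treatment protocol in the labels speaks of 3 treated replicates, while 2 libraries per group are listed, and what became of any other is not given in the sources used here. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. The negative control was labelled 0 h only, so the effect of the TCF7L2 siRNA and that of time since transfection cannot be told apart in comparisons with it.

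The authors deposited 1 table of TPM (length-normalised transcript shares) for 18656 gene symbols, made with RSEM per the submitters' processing notes. Per the same notes the upstream tools were FastQC, Trimmomatic, STAR, Picard and SAMtools, and the genome build was hg19. Tool versions, the gene annotation and strand settings are not given in the sources used here. TPM keeps no read depth, so the depth of each library is unknown and no counting error could be attached to a level. Of the listed symbols, 18409 matched the reference gene names. TPM summed over the listed genes to between 352455.7 and 485601.5 per library, so part of each library lay in genes not analysed here. The lowest sum was that of the second 72 h library. Genes of which reads are shared with a near-identical copy or an overlapping transcript may have been split between them by the authors' estimation, and such genes are named as uncertain.

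From these values, log2(TPM + 1) was computed and genes with TPM of 1 or more in at least 2 libraries were kept, which left 11894. One limma model (version 3.58.1 in R 4.3.3) was fitted to all 8 libraries, with 4 residual degrees of freedom, a mean-variance trend and empirical Bayes moderation. Adjusted p-values are limma's, with Benjamini-Hochberg adjustment over all genes kept, two-sided, at a threshold of 0.05. A fold change is on the log2(TPM + 1) scale and understates the change of low genes. On the TPM as deposited the moderation gave every gene the spread of the trend alone (infinite prior degrees of freedom), with a median standard error (SE) of 0.162, so a gene whose own 2 libraries lay far apart received no larger SE. With each library divided by its median ratio to the mean log profile (median-ratio scaling), the prior degrees of freedom were 5.41 and the median SE 0.0912. The fit to the TPM as deposited was fixed as the main one before the data were examined, with median-ratio scaling among the alternatives. Scaled values are given in part, and most values of single genes are those of the main fit alone.

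Genes were named by a rule fixed before the data were examined. It took the TCF/LEF family in every comparison, and MYC, AXIN2, LGR5, CCND1 and ASCL2 against 0 h. For each comparison with 0 h it took the 8 largest rises and the 8 largest falls with an adjusted p under 0.05, a mean TPM of 5 or more in the higher group and libraries that did not overlap, and between siRNA times the 4 largest each way. For each gene list discussed it took up to 4 members with the smallest p. Of 39 gene lists fixed beforehand, 33 had at least 5 kept genes and were tested with limma's camera at a preset correlation of 0.01, with the p-values adjusted over the lists. Lists with an estimated correlation between genes, and limma's fry, were alternatives. For each list, the number of members called over all genes tested is given, and where stated the number adjusted over the list alone. Another 3 lists had no member among the symbols analysed here.

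Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter or a minimum TPM of 5, median-ratio scaling, quantile normalization, rescaling each library to the same sum over the listed genes, other variance models, a fit to the compared groups alone, the replicate number as a block, other thresholds and leaving out each library. Median-ratio scaling combined with a 2-fold minimum, with an estimated correlation or with the second 72 h library left out was added after seeing the data, as was a split of the 2 control libraries between comparisons. Groups without any change, compared with the same 0 h libraries, were simulated 50 times, for the correlation and covariance that shared controls alone give.

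The limma step was tested on simulated values with 200 changed genes. On values as deposited it recovered 52.2, 50.7 and 55.2% of 1.5-fold changes at 24, 48 and 72 h, 98.5, 100 and 97.0% of 2-fold changes, and 100% of 4-fold changes in each. These ran on 11706, 11706 and 11700 genes, of which 16, 14 and 24 unchanged ones were called. After median-ratio scaling it recovered 94.0, 91.0 and 95.5% of 1.5-fold changes and called 17, 13 and 12 unchanged genes. In a simulation of 33 random lists on 11894 genes, camera called the moved list and 0 of the others. The simulated genes varied independently, so this could not test the preset correlation on lists whose genes vary together.

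A search for 7-base words in 3′ untranslated regions (UTRs) used the GENCODE v29 annotation of GRCh38, with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. For each of 16384 words, the log2 fold change of genes with the word was set against that of genes without it, adjusted for 3′ UTR length and GC content. A Bonferroni limit of 4.667 on the absolute z was used, over 11849 genes with an annotated 3′ UTR, which were 99.62% of those tested. On simulated values for these 11849 genes at 72 h, a planted word with a log2 change of -0.1 was the lowest in 4 of 5 runs, with z from -3.52 to -6.78. With a change of -0.2, a size added after that miss was seen, it was the lowest in 5 of 5 runs. Without a planted word, 0 words passed the limit in the first 5 runs and 1 in the other 5. Coordinates are those of GRCh38 and were not converted to the authors' build. Figures were drawn with matplotlib 3.10.9.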

Results

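Gene expression was measured in SW480 colorectal cancer cells after silencing of TCF7L2, which encodes a transcription factor of the TCF/LEF family through which beta-catenin acts in the Wnt pathway. The 8 libraries comprised 2 of cells given a negative-control siRNA, labelled 0 h, and 2 each of cells given TCF7L2 siRNA for 24, 48 and 72 h. Between 11358 and 11717 genes had a TPM of 1 or more in a library, and the log2 values of the 2 libraries of a group correlated across genes at 0.992 to 0.996. The first principal component held 68.4% of the variance and ordered the groups by time. Listed TPM summed to 464493.2 in the first 72 h library and 352455.7 in the second, while the other 6 libraries had 448107.5 to 485601.5. Log2 fold changes are given ± SE from the fit to all libraries, and TPM as mean ± SD (n = 2).

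The first question was how far the targeted gene fell. TCF7L2 (GRCh38 chromosome 10, 112950250 to 113167678) had 6.86 and 7.47 TPM in the control libraries, 5.82 and 5.05 at 24 h, 4.92 and 4.07 at 48 h, and 4.07 and 3.53 at 72 h. Its log2 fold change against 0 h was -0.35 ± 0.17 at 24 h (adjusted p = 0.637), -0.57 ± 0.17 at 48 h (adjusted p = 0.0111) and -0.77 ± 0.17 at 72 h (adjusted p = 2.98e-05). After median-ratio scaling the 72 h value was -0.58 ± 0.11 (adjusted p = 0.00197). Both 24 h libraries lay below both control libraries, but the 24 h change did not pass the test adjusted over all genes. The 48 h call of TCF7L2 was lost without the first or second 0 h library (adjusted p = 0.123 and 0.27) or 48 h library (0.0602 and 0.391). LEF1, another member of the family (chromosome 4, 108047545 to 108168956), had 17.4 ± 3.82 TPM in the control and 18.3 ± 1.51 at 24 h, and rose to 31.5 ± 2.65 at 48 h and 53.3 ± 4.09 at 72 h. The log2 change of LEF1 was 0.83 ± 0.16 at 48 h (adjusted p = 1.61e-05) and 1.58 ± 0.16 at 72 h (adjusted p = 7.25e-21). Its 48 h call was lost when the second control library was left out (adjusted p = 0.154). TCF7 had 8.64 ± 0.212 TPM at 0 h and 7.36 ± 0.198 at 72 h (log2 change -0.21 ± 0.16, adjusted p = 0.313), and TCF7L1 was below 1 TPM in every library.

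Among the Wnt target genes chosen beforehand, MYC had 441 ± 0.912 TPM at 0 h, 346 ± 7.56 at 24 h, 329 ± 2.09 at 48 h and 232 ± 31.3 at 72 h, where it fell by 0.93 ± 0.17 on the log2 scale (adjusted p = 6.31e-07). CCND1, which encodes cyclin D1, went from 148 ± 0.474 to 78.1 ± 12.3 TPM at 72 h (log2 change -0.92 ± 0.16, adjusted p = 2.7e-07). ASCL2, a stem-cell transcription factor, went from 40.2 ± 0.247 to 23.4 ± 3.18 (-0.76 ± 0.16, adjusted p = 1.68e-05). AXIN2, a feedback inhibitor of the pathway, fell from 216 ± 4.35 to 160 ± 25.9 TPM (-0.45 ± 0.17, adjusted p = 0.0205). The AXIN2 call was lost in 7 of 21 alternatives, among them leaving out the first or second 0 h library (adjusted p = 0.196 and 0.155), 24 h library (0.0611 and 0.0609) or 48 h library (0.0649 and 0.0648). LGR5 stayed below 1.5 TPM in all libraries (log2 change at 72 h -0.30 ± 0.18, adjusted p = 0.154). At 24 and 48 h these genes did not pass the test on the TPM as deposited. After median-ratio scaling MYC passed at both times (adjusted p = 0.031 and 0.000291), and AXIN2 and CCND1 passed at 48 h (adjusted p = 0.00928 and 0.00472).

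**Figure D1:**
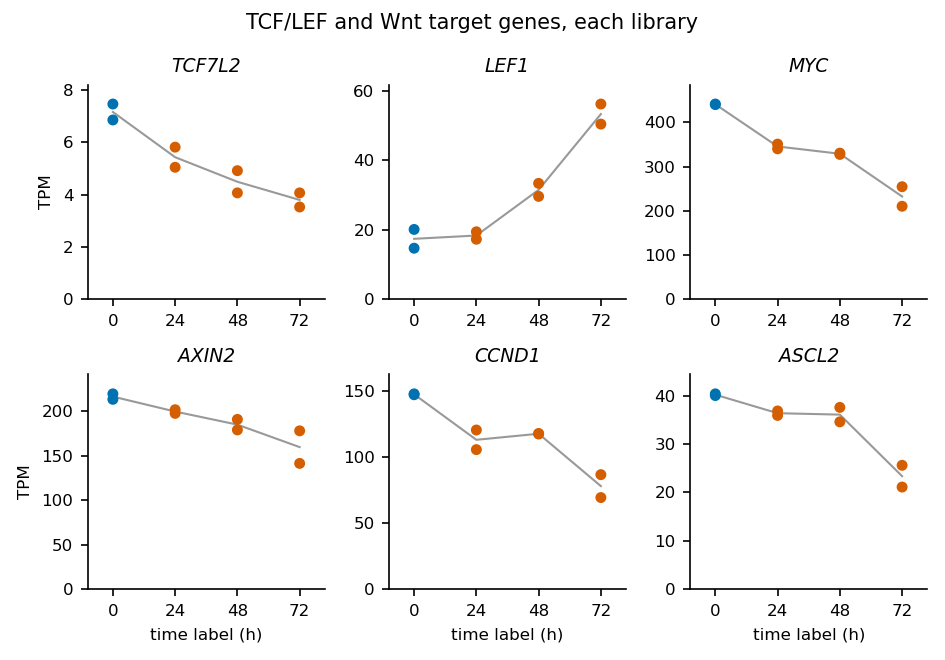
TPM (vertical axes, starting at 0) of 6 genes in each library against its time label in hours (horizontal axes), with 1 point per library, control siRNA in blue, TCF7L2 siRNA in orange, and lines through the means of 2 libraries. TCF7L2 declined from 6.86 and 7.47 TPM to 4.07 and 3.53, MYC from 441 ± 0.912 to 232 ± 31.3, and LEF1 rose from 17.4 ± 3.82 to 53.3 ± 4.09.

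At 24 h against 0 h, 55 of 11894 genes were called on the TPM as deposited and 129 after median-ratio scaling. The SE as deposited was pooled over all libraries, the 72 h ones included, so smaller changes may have been missed. CDKN1A, which encodes the CDK inhibitor p21, fell from 14.5 ± 0.573 to 7.88 ± 0.148 TPM (log2 change -0.81 ± 0.16, adjusted p = 0.000506). GDF15, a stress-induced cytokine, fell by 0.68 ± 0.16, IL23A, a subunit of interleukin 23, by 0.68 ± 0.16, METRNL by 0.69 ± 0.17, ID2, an inhibitor of bHLH factors, by 0.69 ± 0.16, AMH by 0.74 ± 0.17 and TAGLN by 0.76 ± 0.17. Among the rises were DSC2, a desmosomal cadherin, from 3.44 ± 0.262 to 6.69 ± 0.311 TPM (0.79 ± 0.16, adjusted p = 0.000796). The sulfotransferase gene SULT2B1 (0.79 ± 0.16), SMIM15 (0.76 ± 0.16) and PHGR1, an intestinal epithelial gene (0.96 ± 0.16), rose too. The decoy receptor gene TNFRSF6B rose by 1.13 ± 0.16. TNFRSF6B overlaps a neighbouring transcription unit and is uncertain, as are PIGY (-2.46 ± 0.17), which shares a transcript with PYURF, and the readthrough gene ATP6V1G2-DDX39B (1.12 ± 0.17). For PIGY, ATP6V1G2-DDX39B, PLCB1 (1.09 ± 0.16) and CNBD2 (1.06 ± 0.17), the 2 libraries of 1 group lay far apart, as in PLCB1 with 15.8 ± 13.8 TPM at 24 h. The calls of these 4 genes, and those of TAGLN, AMH and ID2, did not hold after median-ratio scaling. Those of the 4 genes were also lost without the first or second 72 h library (for PIGY adjusted p = 0.11 in both). Without the first 24 h library the changes of PLCB1 and ATP6V1G2-DDX39B shrank to 0.13 and 0.46, and their calls were lost. Without the second 0 h library those of CNBD2 and ATP6V1G2-DDX39B shrank to 0.19 and 0.80, and their calls were lost. The call of CDKN1A was lost without the first or second 0 h library (adjusted p = 0.106 and 0.226) or 24 h library (0.113 and 0.122). So were those of GDF15, IL23A, METRNL, ID2, DSC2 (from 0.0888 to 0.398), SULT2B1 and SMIM15, those of AMH without either 0 h or the first 24 h library, and those of TAGLN without the first 0 h or either 24 h library. Without either 48 h library those of GDF15 (0.0588 and 0.0591), IL23A and ID2 (each 0.0516 and 0.0511) were lost too. That of PHGR1 was lost without the second 0 h library (adjusted p = 0.118) or the first 24 h library (0.0855), and that of TNFRSF6B without the first 0 h library (0.277).

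In total 55 of 11894 genes were called at 24 h, 25 higher and 30 lower (45.5% higher), and 129 after median-ratio scaling, 77 higher and 52 lower (59.7% higher). Of these, 25 were called in both with the same sign. The median of all genes was -0.09 as deposited and 0.00 after scaling. Leaving out the first or second library gave 13 or 14 genes at 0 h, 10 or 26 at 24 h, 31 or 31 at 48 h, and 740 or 738 at 72 h, with a lone library assumed to vary like the other groups.

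By camera, 13 of 33 lists were called at 24 h, 0 of them with an estimated correlation. The absorptive enterocyte and colonocyte list had 2 of 17 members higher and 0 lower (4 and 0 adjusted over the list alone), with a median log2 change of 0.19. The adjusted p was 5.53e-13, and 0.599 with an estimated correlation. PHGR1 rose as above and CDH17, an intestinal cadherin, rose by 0.69 ± 0.16, while CDHR2 (0.55 ± 0.16, adjusted p = 0.122) and MYO1A (0.47 ± 0.17, adjusted p = 0.332) did not pass. The S-phase list had 0 of 52 members higher and 1 lower (0 and 4 over the list alone; median -0.29), namely CCNE1, which encodes cyclin E1 (-0.65 ± 0.16, adjusted p = 0.0266). The list had an adjusted p of 2.21e-11, and 0.963 with an estimated correlation. After median-ratio scaling 20 members of the S-phase list were lower over the list alone, and the adjusted p was 4.78e-13, and 0.0435 with an estimated correlation. The cytosolic ribosomal protein list (76 genes, median 0.05) was higher with an adjusted p of 2.29e-06 and the G2/M list (51 genes, median 0.03) with 0.00198, each at an adjusted p of 0.963 with an estimated correlation and with 0 members called, over all genes or adjusted over the list alone. After scaling 4 and 1 members of these lists were higher over all genes, and 50 and 9 adjusted over the list alone. Immediate early genes (median -0.30), cholesterol biosynthesis genes (-0.25) and Notch pathway genes (-0.22) were lower as lists, with adjusted p-values of 2.16e-05, 3.01e-05 and 0.00314. With an estimated correlation the adjusted p of all 3 was 0.963, and 0 members of any were called over all genes, against 5, 3 and 1 lower ones adjusted over each list alone. The YAP/TAZ, ribosome biogenesis, CDK inhibitor, ATF4 and TGF-beta lists were lower with adjusted p-values of 0.0147, 0.0153, 0.0182, 0.0182 and 0.0223, and the oxidative phosphorylation list, with a median of 0.00, was higher with 0.0221. With an estimated correlation the adjusted p of each was 0.963. Of their members 0, 0, 1, 0, 2 and 0 were called over all genes, and 1, 0, 2, 1, 2 and 0 adjusted over each list alone. Of 47 Wnt target genes 0 were higher and 1 lower (adjusted p = 0.293).

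At 48 h against 0 h the largest rises were in ENC1, which encodes an actin-binding protein, from 2.96 ± 0.297 to 20.6 ± 0.552 TPM (log2 change 2.45 ± 0.16, adjusted p = 1.76e-47), and in the metallothionein gene MT4 (2.36 ± 0.16). CD44, a hyaluronan receptor, rose from 12.4 ± 0.509 to 49.5 ± 5.4 TPM (1.90 ± 0.16, adjusted p = 2.16e-29). The acyl-CoA synthetase gene ACSL5 rose by 1.93 ± 0.16, the enamel matrix gene AMBN by 2.03 ± 0.17 and LMNTD1 by 1.83 ± 0.16. TNFRSF6B (1.97 ± 0.16) and ATP6V1G2-DDX39B (1.87 ± 0.17) were again higher. The falls included MLXIPL, which encodes the carbohydrate-response factor ChREBP, from 31.3 ± 1.69 to 14.2 ± 1.22 TPM (-1.09 ± 0.16, adjusted p = 2.06e-09). YES1, a SRC-family kinase gene, fell from 49.4 ± 2.16 to 23.4 ± 1.53 (-1.04 ± 0.16, adjusted p = 1.21e-08). IDUA, from 12.1 to 5.56 TPM, PKD1 (-1.05 ± 0.16), IZUMO1 (-1.06 ± 0.17) and AMH (-1.51 ± 0.17) also fell. NPIPB5 (-1.30 ± 0.16), 1 of a family of near-identical genes, and PIGY (-1.31 ± 0.17) are uncertain, and the PIGY call did not hold after median-ratio scaling. Without the first 48 h library the change of PIGY was -0.56 ± 0.22 (adjusted p = 0.196), and its call was also lost without the first or second 72 h library (0.28 in both).

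In total 922 genes were called at 48 h, 548 higher and 374 lower (59.4% higher), and 2797 after median-ratio scaling, 1428 higher and 1369 lower (51.1% higher), of which 849 were called in both with the same sign. Leaving out the first or second library gave 278 or 302 genes at 0 h, 611 or 611 at 24 h, 320 or 292 at 48 h, and 3142 or 3146 at 72 h.

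Of the 33 lists, 9 were called at 48 h, 0 of them with an estimated correlation. In the absorptive enterocyte and colonocyte list 12 of 17 members rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 0.83. It had an adjusted p of 1.1e-24, and 0.197 with an estimated correlation. After median-ratio scaling these were 8.44e-10 and an adjusted p of 0.039 with an estimated correlation. CEACAM6, a carcinoembryonic antigen family gene, rose by 1.59 ± 0.17, CDH17 by 1.33 ± 0.16, PHGR1 by 1.32 ± 0.16 and CEACAM1 by 1.19 ± 0.17. The S-phase list had 0 of 52 members higher and 7 lower (0 and 9 over the list alone; median -0.28), among them POLE, a DNA polymerase gene (-0.66 ± 0.16), and GINS4 (-0.79 ± 0.17). This gave an adjusted p of 2.18e-07, and 0.999 with an estimated correlation, against 0.039 with an estimated correlation after scaling. The mesenchymal list had 3 of 27 members higher and 1 lower (4 and 1 over the list alone), with an adjusted p of 0.000436, and 0.999 with an estimated correlation. CD44, the protease gene PLAU (0.84 ± 0.17) and the matrix gene TGFBI (0.61 ± 0.16) were the higher ones, and TAGLN (-0.72 ± 0.17, not called after scaling) the lower. The epithelial list had 7 of 38 higher and 1 lower (8 and 1 over the list alone; adjusted p = 0.00872, and adjusted p = 0.999 with an estimated correlation), with DSC2 at 1.79 ± 0.16 and the keratin gene KRT20 at 0.85 ± 0.17. The ribosomal protein list (median 0.20; adjusted p = 0.000433, and adjusted p = 0.999 with an estimated correlation) had 0 of 76 members called, over all genes or over the list alone, and 55 higher after scaling. The ribosome biogenesis list had 2 of 51 lower (1 over the list alone; adjusted p = 0.000436, and adjusted p = 0.999 with an estimated correlation), and 20 after scaling. The TGF-beta (adjusted p = 0.04), stem cell (0.0315) and Notch (0.0494) lists were called with an adjusted p of 0.999 with an estimated correlation, and the last 2 not after scaling (0.334 and 0.108). They had 4 higher and 3 lower, 4 and 1, and 0 and 2 members over all genes, and 5 and 3, 5 and 2, and 0 and 3 adjusted over the list alone. Of 47 Wnt target genes 9 rose and 4 fell (11 and 5 over the list alone, 13 and 12 after scaling; adjusted p = 0.21), with FGF20 at 1.02 ± 0.16 and PLAUR at 0.88 ± 0.16.

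At 72 h against 0 h the changes were larger. As deposited they include a median shift of all genes of -0.19, which was 0.00 after median-ratio scaling. TRIB3, a pseudokinase gene induced in the integrated stress response, fell from 327 ± 0.849 to 28.0 ± 6.19 TPM (log2 change -3.51 ± 0.16, adjusted p = 7.53e-97). COX7C, a subunit of cytochrome c oxidase, fell from 281 ± 0.785 to 31.4 ± 6.77 TPM (-3.14 ± 0.16, adjusted p = 3.93e-78). After scaling its log2 change was -2.92 (limma adjusted p = 6e-10). CST7, which encodes cystatin F, fell from 46.5 ± 0.552 to 3.80 ± 1.04 (-3.32 ± 0.16), and YES1 from 49.4 ± 2.16 to 5.62 ± 1.1 (-2.94 ± 0.16). The stress-induced genes DDIT4 (-2.60 ± 0.16), GDF15 (-2.77 ± 0.16) and FGF21 (-2.67 ± 0.16) fell too, as did MEF2B (-2.83 ± 0.16), which is uncertain because it overlaps a readthrough gene. CD44 rose from 12.4 ± 0.509 to 115 ± 2.09 TPM (3.11 ± 0.16, adjusted p = 8.39e-81). ENC1 rose from 2.96 ± 0.297 to 40.5 ± 8.39 (3.38 ± 0.16), and SOX2, a pluripotency transcription factor gene, from 2.60 ± 0.559 to 25.5 ± 3.68 (2.88 ± 0.16). TM4SF4, from 0.185 ± 0.191 to 11.6 ± 1.56 TPM, rose by 3.42 ± 0.17, FDCSP by 3.27 ± 0.17, LMNTD1 by 3.13 ± 0.16, CEACAM6 by 3.01 ± 0.17 and ZPLD1 by 2.83 ± 0.17.

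**Figure D2:**
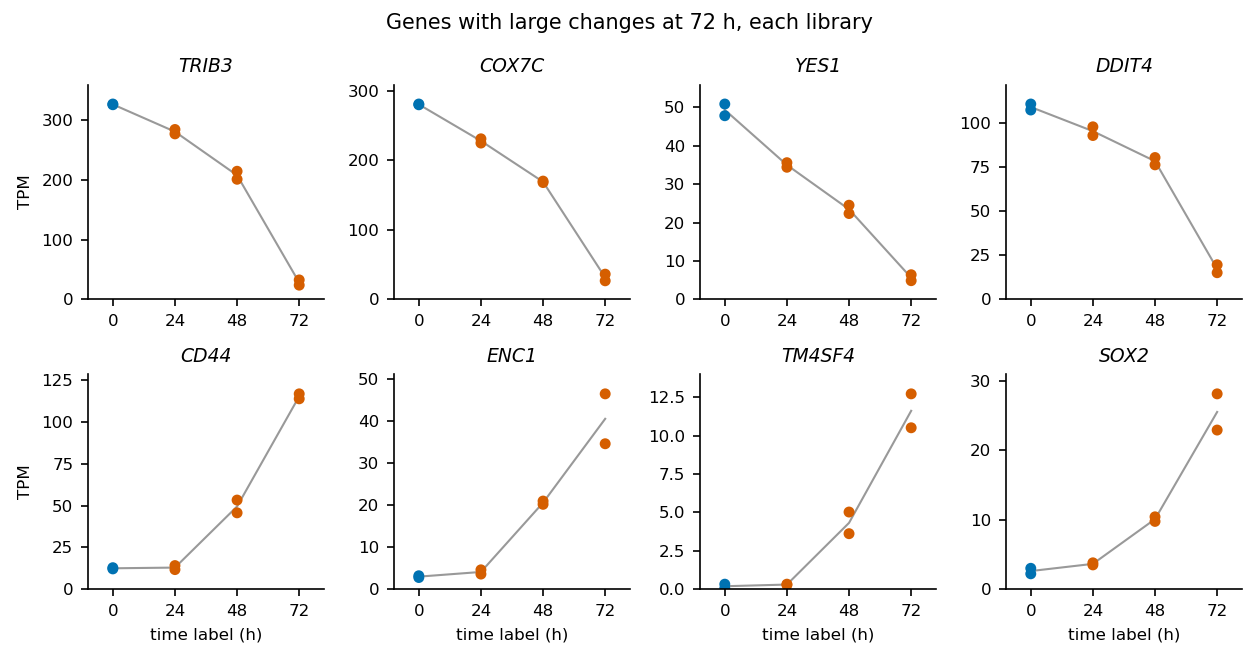
TPM (vertical axes, starting at 0) of 8 genes with large changes at 72 h in each library against its time label in hours (horizontal axes), with 1 point per library, control siRNA in blue, TCF7L2 siRNA in orange, and lines through the means of 2 libraries. TRIB3 had 327 ± 0.849 TPM at 0 h and 28.0 ± 6.19 at 72 h, and CD44 12.4 ± 0.509 and 115 ± 2.09.

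In total 4968 genes were called at 72 h, 1253 higher and 3715 lower (25.2% higher). After median-ratio scaling 6179 were called, 3064 higher and 3115 lower (49.6% higher), and 4328 were called in both with the same sign. The median of all genes was -0.19 as deposited and 0.00 after scaling, so the excess of lower genes was relative to that shift. A change of 2-fold or more was called in 588 genes, 257 higher and 331 lower, and after scaling in 541, 380 higher and 161 lower, so the direction of the excess turned. Leaving out the first or second 0 h library gave 2870 or 2662 genes, and leaving out the first 72 h library 7658, 982 higher and 6676 lower. Without the second 72 h library, whose listed TPM sum was the lowest, 2380 were higher and 3024 lower.

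Of the 33 lists, 10 were called at 72 h, 0 of them with an estimated correlation. In the ATF4 and unfolded protein response list 0 of 35 members were higher and 23 lower (1 and 24 adjusted over the list alone), with a median of -0.87, and 7 and 24 after median-ratio scaling, with a median of -0.65. The camera adjusted p was 2.74e-11, and 0.992 with an estimated correlation. TRIB3 and DDIT4 were followed by the transcription factor genes CEBPB (-2.24 ± 0.16) and DDIT3 (-1.83 ± 0.16). The absorptive enterocyte and colonocyte list had 11 of 17 members higher and 1 lower (11 and 1 over the list alone; median 0.94), with an adjusted p of 2.6e-13, and 0.575 with an estimated correlation. CEACAM5 (2.27 ± 0.18), the mucin gene MUC13 (1.76 ± 0.16) and CEACAM1 (1.75 ± 0.17) rose beside CEACAM6. In the S-phase list 0 of 52 members rose and 43 fell (0 and 44 over the list alone; 0 and 38 after scaling), among them TK1, thymidine kinase (-1.22 ± 0.16), EXO1 (-1.04 ± 0.16) and E2F2 (-1.04 ± 0.17). By camera the adjusted p was 4.23e-06, and 0.992 with an estimated correlation. In the ribosome biogenesis and MYC-responsive list 0 of 51 rose and 35 fell (0 and 36 over the list alone; 2 and 35 after scaling), with DDX21, an RNA helicase gene, at -1.42 ± 0.16 and NME1 at -0.83 ± 0.17. The adjusted p was 0.00111, and 0.992 with an estimated correlation. In the mesenchymal list 12 of 27 rose and 5 fell (13 and 5 over the list alone), with VIM, which encodes vimentin, at 1.26 ± 0.16, TNC at 1.23 ± 0.17 and THBS1 at 1.24 ± 0.17. The list had an adjusted p of 1.5e-05, and 0.992 with an estimated correlation.

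The type I interferon list had 9 of 31 members higher and 2 lower at 72 h (9 and 2 over the list alone), with ISG20 at 1.09 ± 0.16 and OAS1 at 1.04 ± 0.17, and IRF1 lower (-0.63 ± 0.16). It had an adjusted p of 0.00952, and 0.992 with an estimated correlation. In the Notch list 0 of 23 rose and 11 fell (1 and 11 over the list alone; adjusted p = 0.0119, and adjusted p = 0.992 with an estimated correlation), with HES5 at -1.85 ± 0.16 and NOTCH1 at -1.28 ± 0.16. In the G2/M list 0 of 51 rose and 23 fell (0 and 23 over the list alone; adjusted p = 0.0262, and adjusted p = 0.992 with an estimated correlation), while 4 rose and 22 fell after scaling. The NF-kB list had 6 of 17 higher and 4 lower (8 and 5 over the list alone; adjusted p = 0.0245, and adjusted p = 0.992 with an estimated correlation), and was not called after scaling (0.167), as the Notch list was not (0.085). The intestinal stem cell list was called higher (adjusted p = 0.00584, and adjusted p = 0.992 with an estimated correlation) although its median was -0.31, with CD44, PTPRO (1.76 ± 0.17), ALCAM (1.60 ± 0.16) and MYB (1.28 ± 0.16) higher and 7 of 19 members lower, ASCL2 and AXIN2 among them. After scaling its adjusted p was 0.394. Of 47 Wnt target genes, 12 rose and 21 fell (13 and 24 over the list alone), and the list was not called (adjusted p = 0.443). Its median was -0.35 although the test pointed up, and after scaling the test pointed down (adjusted p = 0.852). FGF20 (1.67 ± 0.16) and PLAUR (1.31 ± 0.16) rose beside LEF1 and CD44, and MYC, CCND1, ASCL2 and AXIN2 fell. The housekeeping list had 1 of 26 members higher and 10 lower (adjusted p = 0.572), or 4 and 8 after scaling. The chromatin architecture list, of CTCF and cohesin genes, had 2 of 32 members higher and 17 lower (2 and 18 over the list alone; adjusted p = 0.383). The ribosomal protein list had a median of -0.11 as deposited and 0.11 after scaling, so its direction turned with the scaling.

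**Figure D3:**
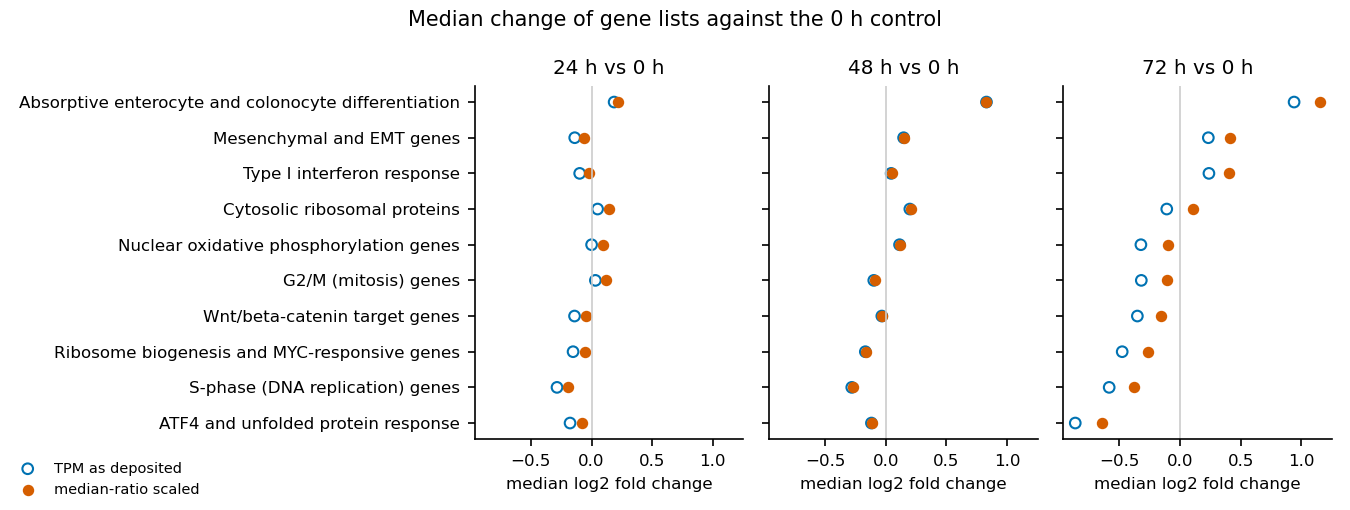
Median log2 fold change (horizontal axes) of 10 gene lists (vertical axis) at 24, 48 and 72 h against 0 h, with open blue circles for TPM as deposited and filled orange circles after median-ratio scaling, without error bars. At 72 h the medians ranged from -0.87 for the ATF4 and unfolded protein response list to 0.94 for the absorptive enterocyte and colonocyte list as deposited, and from -0.65 to 1.15 after scaling, where the ribosomal protein list turned from -0.11 to 0.11.

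Fold changes between siRNA times do not involve the 0 h control, though its libraries enter the shared spread and so the calls. From 24 to 48 h ENC1 rose by 2.09 ± 0.16, CD44 by 1.86 ± 0.16, AMBN by 1.86 ± 0.17, the semaphorin gene SEMA3C by 1.82 ± 0.16 and LEF1 by 0.75 ± 0.16, while MLXIPL (-0.81 ± 0.16) and ZACN (-0.77 ± 0.17) fell. NPIPB5 (-0.95 ± 0.16) and SMIM11A (-1.51 ± 0.16) are uncertain, the latter because of a near-identical copy and 24 h libraries that lay far apart (SD 13.3 TPM). The SMIM11A call did not hold after scaling, nor without the first 24 h library or either 72 h library. Calls were lost for LEF1 without the second 24 h or first 48 h library (adjusted p = 0.119 and 0.116). They were lost without the first 24 h or first 48 h library for MLXIPL (0.0743 and 0.0558). The latter pair also ended the calls of ZACN (0.0567 and 0.291) and NPIPB5 (0.0857 and 0.286). From 48 to 72 h TRIB3 (-2.86 ± 0.16), CST7 (-2.77 ± 0.16), COX7C (-2.41 ± 0.16) and MEF2B (-2.27 ± 0.16) fell, and FDCSP (1.98 ± 0.17), COX6B2 (1.84 ± 0.16), ZPLD1 (1.68 ± 0.17), HTN3 (1.65 ± 0.17) and LEF1 (0.74 ± 0.16) rose. From 24 to 72 h CALCB, which encodes a calcitonin gene-related peptide, fell by 2.68 ± 0.16, CST7 by 3.34 ± 0.16, TRIB3 by 3.30 ± 0.16 and COX7C by 2.84 ± 0.16, and TM4SF4 (3.28 ± 0.17), FDCSP (3.12 ± 0.17), CD44 (3.07 ± 0.16), ENC1 (3.02 ± 0.16) and LEF1 (1.49 ± 0.16) rose. TCF7L2 had log2 changes of -0.23 ± 0.17 from 24 to 48 h (adjusted p = 0.587), -0.19 ± 0.17 from 48 to 72 h (adjusted p = 0.398) and -0.42 ± 0.17 from 24 to 72 h (adjusted p = 0.0345). The last call was lost in 10 of 21 alternatives, among them leaving out any single library but the first 72 h one (adjusted p from 0.0629, without the second 48 h library, to 0.314, without the first 24 h library).

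Of the genes tested between siRNA times, 512 were higher and 85 lower from 24 to 48 h (85.8% higher), 590 and 2621 from 48 to 72 h (18.4% higher), and 1429 and 2548 from 24 to 72 h (35.9% higher). After median-ratio scaling these were 899 and 769 (53.9% higher), 2439 and 2312 (51.3% higher), and 2965 and 2992 (49.8% higher). The median change of all genes from 48 to 72 h was -0.17 as deposited and 0.02 after scaling. The counts of list members for that step below are as deposited, so they include this shift. The CDK inhibitor and senescence list rose from 24 to 48 h, with 8 of 18 members higher and 0 lower (9 and 0 over the list alone; adjusted p = 2.4e-05, and adjusted p = 0.964 with an estimated correlation). From 48 to 72 h the ATF4 and unfolded protein response list had 0 of 35 members higher and 22 lower (0 and 23 over the list alone; adjusted p = 5.28e-14, and adjusted p = 0.982 with an estimated correlation), and the nuclear oxidative phosphorylation list 0 of 51 higher and 30 lower (0 and 33 over the list alone; adjusted p = 2.67e-05, and adjusted p = 0.982 with an estimated correlation). The F test over the 3 siRNA times called 4811 genes, and 3135 without the second or 3168 without the first 0 h library, and 8288 without the first 72 h library. Without the first or second 24 h library, 162 or 188 genes were called from 24 to 48 h and 1971 or 1974 from 24 to 72 h. Without the first or second 48 h library, 225 or 203 were called from 24 to 48 h and 1254 or 955 from 48 to 72 h. Without the first or second 72 h library these counts were 2290 or 2297 from 24 to 48 h, 6856 or 3643 from 48 to 72 h, and 6777 or 5006 from 24 to 72 h.

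The comparisons with 0 h share its 2 libraries, so their fold changes agree in part by chance. Genes called at both 48 and 72 h numbered 458 higher, 298 lower and 9 in opposite directions, where independent lists would give 57.7 and 117. Unchanged groups gave at most 0 in 50 simulations. With no changed gene they yield almost no calls, so they set no chance level for shared calls. The correlation across genes of the 48 and 72 h fold changes was 0.713, against 0.499 simulated, and their covariance 0.1, against 0.0134. For 24 and 48 h these were 0.544 against 0.499 and 0.0255 against 0.0135, with 15 genes higher, 10 lower and 2 in opposite directions, where independent lists would give 1.15 and 0.943. For 24 and 72 h they were 0.350 against 0.500 and 0.0288 against 0.0134, with 16 and 20 genes and 4 in opposite directions, where independent lists would give 2.63 and 9.37. The correlation between 24 and 72 h was thus below the simulated one, while the covariance was above it. The simulated correlation is that of unchanged groups of like spread, so it is no chance level for groups that changed. The lower correlation therefore does not show less agreement than chance. With 1 control library given to each comparison, a check added after seeing the data, the covariance was 0.0927 or 0.0951 for 48 and 72 h, 0.0191 or 0.0188 for 24 and 48 h, and 0.0213 or 0.0234 for 24 and 72 h. The genes called in both then numbered 199 or 170 higher and 44 or 41 lower at 48 and 72 h, where independent lists would give 15.8 or 14.4 and 12.5 or 9.62. In opposite directions there were 6 or 1. At 24 and 48 h they numbered 2 or 4 higher, 1 or 1 lower and 1 or 1 opposite, where independent lists would give 0.073 or 0.194 and 0.0516 or 0.0183. At 24 and 72 h they numbered 2 or 4 higher, 3 or 2 lower and 3 or 0 opposite, against 0.275 or 0.666 and 1.73 or 0.473. Each split comparison rests on a lone control library, assumed to vary like the other groups. In the comparisons with both control libraries, part of the excess may come from the shared libraries.

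Markers of other cell types were mostly below 1 TPM, among them the leukocyte gene PTPRC, which reached 0.63 TPM at most, and the endothelial gene PECAM1, 0.34 at most. Some moved with time. CD68, a lysosomal gene of macrophages, rose from 2.85 to 20.5 TPM at 72 h (log2 change 2.50 ± 0.16), LYZ, lysozyme, from 2.07 to 7.58 (1.48 ± 0.17), LUM, lumican, from 9.18 to 37.3 (1.88 ± 0.16) and COL3A1 from 0.015 to 2.26 (1.67 ± 0.18). COL1A1, the abundant fibroblast collagen, was 1.58 TPM at 0 h and 2.85 at 72 h (0.59 ± 0.17), and HBA1 was 6.63 and 4.04 (-0.61 ± 0.16, not called after scaling).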

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

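The tests of the difference between the 72 h and 24 h effects were planned as the comparison of 72 with 24 h, and which genes to list here followed from the named genes. The effect against 0 h differed between 24 and 72 h, in the TPM as deposited and after median-ratio scaling, for 35 of 47 named genes, 17 with a higher value at 72 h and 18 with a lower one. Most of these genes had been named for large changes against 0 h in the same libraries, so this share was partly set by that choice. Over all 11894 genes, 3825 were called with the same sign in both scalings, 1406 higher and 2419 lower at 72 h. Because both effects share the 0 h libraries, the difference is that between the 72 h and 24 h libraries. No test for outlying libraries was run in groups of 2. The second 72 h library stood apart in its listed TPM sum of 352455.7 and its log2 scaling offset of -0.314.

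Among the genes of the Wnt pathway, the log2 difference (72 h effect minus 24 h effect) was -0.42 for TCF7L2, 1.49 for LEF1, -0.58 for MYC, -0.54 for CCND1, -0.62 for ASCL2 and 3.07 for CD44. It was -3.3 for TRIB3, -2.41 for DDIT4, -2.09 for GDF15 and -2.15 for FGF21, genes of stress responses, and -2.84 for COX7C, -3.34 for CST7, -2.45 for YES1, -2.45 for MEF2B, -1.19 for MLXIPL, -1.75 for IZUMO1, -0.95 for PKD1, -1.06 for AMH and -0.53 for SMIM15. Higher values at 72 h were 3.02 for ENC1, 3.28 for TM4SF4, 3.12 for FDCSP, 2.93 for ZPLD1, 2.81 for CEACAM6, 2.67 for LMNTD1, 2.61 for AMBN, 2.51 for SOX2, 2.08 for ACSL5, 1.44 for DSC2, 1.2 for MT4, 1.11 for TNFRSF6B, 0.94 for ATP6V1G2-DDX39B, 1.03 for IL23A and 0.7 for CDKN1A. SULT2B1, with a difference of -1.52, was called in opposite directions at 24 h (0.79) and 72 h (-0.73). No explanation was tested for these differences beyond those below.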

How the results depend on the processing

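Of 102 results for single named genes, 67 were alike in every alternative, called or not, 29 were lost and 6 gained in at least 1, and 0 reversed. The 67 include results that stayed uncalled throughout, such as those of LGR5 against 0 h and TCF7 at 72 h against 0 h. Many of the others had been named for the largest changes in the main fit, and TCF7L2 against 0 h was not among the 102. Counts moved more. At 24 h against 0 h, 55 genes became 0 without a filter (limma, where 849 had an unadjusted p under 0.05 with the filter), 30 at a TPM of 5, 129 after median-ratio scaling, 110 after quantile normalization, 170 rescaled to equal sums, 91 with block and scaling, 296 scaled without the second 72 h library, 607 in a fit to the compared groups, 7 at 2-fold, 27 at an adjusted p under 0.01 and 2 scaled at 2-fold. In the same order 922 genes at 48 h became 199, 604, 2797, 2625, 3191, 2707, 3147, 3046, 82, 521 and 77. The 4968 at 72 h became 2704 in a fit to the compared groups, 588 at 2-fold and 541 scaled at 2-fold. From 24 to 48 h, 597 became 84, 387, 1668, 1554, 1745, 1565, 1955, 2107, 54 and 343 in the first order up to an adjusted p under 0.01. From 48 to 72 h, 3211 became 1599 without a filter, 4846 rescaled to equal sums, 959 in a fit to the compared groups, 184 at 2-fold and 1885 at an adjusted p under 0.01. From 24 to 72 h, 3977 became 5974 after quantile normalization, 1932 in a fit to the compared groups and 445 at 2-fold. The F test's 4811 became 2649 without a filter, where TCF7L2 at 48 h, at -0.57, was not called; nor was it without the first or second 0 h library (-0.63 and -0.52) or 48 h library (-0.69 and -0.46). Lists called by camera at 24 h went from 13 to 0 with an estimated correlation, 0 by fry, 12 by fry with scaling and 1 with scaling and an estimated correlation; at 48 h from 9 to 0, 1, 17 and 2; at 72 h from 10 to 0, 2, 26 and 0, and to 6 at a TPM of 5. Genes called at both 24 and 48 h went from 25 to 133 at an unadjusted p under 0.01 and 106 scaled, at 24 and 72 h from 36 to 171 and 84, and at 48 and 72 h from 756 to 2101 scaled. With the control libraries split these became 3 or 5, 5 or 6, and 243 or 211.

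Without a filter more genes were tested and the prior degrees of freedom fell from infinite to 3.61, and these changes were not separated. With a fit to the compared groups fewer libraries set the spread. After median-ratio scaling, quantile normalization and rescaling to equal sums the prior degrees of freedom were 5.41, 5.13 and 5.26. Without the first or second 72 h library they were 5.55 and 5.57. The cause of the moves in the counts was not tested. Leaving out a library, with a lone library assumed to vary like the other groups, gave 10 to 740 genes at 24 h, 278 to 3146 at 48 h, 2662 to 7658 at 72 h, 162 to 2297 from 24 to 48 h, 955 to 6856 from 48 to 72 h, 1971 to 6777 from 24 to 72 h and 3135 to 8288 by the F test. Lists ranged from 8 to 13, 6 to 10 and 8 to 14, and TCF7L2 from -0.43 to -0.26, -0.69 to -0.46 and -0.85 to -0.69. Replicate numbers did not pair the libraries (correlations of deviations across genes -0.085 to 0.106); with the replicate as a block the counts were 51, 864 and 4860 against 0 h and 571, 3088 and 3867 between siRNA times. The scaled fits at 2-fold, with fry, with an estimated correlation or without the second 72 h library, and the split controls, were chosen after seeing the data. Depth was unknown, so no limit of detection could be given.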

Other observations

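The tests of named pathways were planned, and all tests of 3′ UTR words except the first, a search for seed matches at 72 h, were chosen after the result was seen. At 72 h against 0 h SLC2A1, which encodes the glucose transporter GLUT1, fell from 340 ± 0.856 to 82.3 ± 16.7 TPM (log2 change -2.05 ± 0.17) and VEGFA fell by 1.21 ± 0.16. Of 38 genes of glycolysis and hypoxia 1 rose and 18 fell (1 and 18 adjusted over the list alone), and 6 rose and 15 fell after median-ratio scaling, while the list was not called (adjusted p = 0.206). Of 51 nuclear oxidative phosphorylation genes 1 rose and 21 fell (1 and 21 over the list alone; adjusted p = 0.0522), and 14 rose and 20 fell after scaling. Guidance genes went both ways, with SEMA3C (2.56 ± 0.16) and its receptor gene NRP1 (1.80 ± 0.17) higher and UNC5B (-1.97 ± 0.16) lower, 7 higher and 8 lower of 26 in all (7 and 9 over the list alone; adjusted p = 0.216).

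Among 34 apoptosis regulators 6 rose and 13 fell (6 and 13 over the list alone; adjusted p = 0.991), with BCL2L1, which encodes BCL-XL, at -1.13 ± 0.16. After scaling 8 rose and 8 fell. Of 27 p53 target genes 5 rose and 12 fell (5 and 12 over the list alone; adjusted p = 0.534), with SESN2 at -1.46 ± 0.16, TNFRSF10B at -1.24 ± 0.16 and BBC3 at -1.11 ± 0.16. In the small interfering RNA machinery AGO1 was at -1.02 ± 0.16 and TNRC6A at 0.79 ± 0.16, with 1 higher and 4 lower of 13 (1 and 4 over the list alone; adjusted p = 0.732).

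Part of the fall at 72 h may come from seed matches of the TCF7L2 siRNA in other transcripts. Among all words of 7 bases, ACTAGAT in 3′ UTRs had the lowest z, -9.69 over 856 genes (limit 4.667), against 5.40 for the highest word and a lowest z of -3.14 over 417 other arrangements of its bases, which argues against base composition (left out were CTAGATA, -8.23, and TACTAGA, -3.87, which overlap it by 6 bases; in genes without either word of the site TACTAGA was at -0.96). Its z was -1.60 at 24 h, within the limit although the siRNA was present, and -7.95 at 48 h; it lies in TCF7L2 (GRCh38 chromosome 10, 113165630 to 113165636), as 30.44% of all words do, but CTAGATA, the other word of the 8-base site, does not, and the siRNA sequence is not given in the sources used here. The 223 genes with the 8-base site ACTAGATA had a median log2 change of -0.31. It was -0.26 and -0.21 for either 7-base site alone and -0.19 without a site. After scaling these medians were -0.11, -0.07, -0.03 and 0.01. The bootstrap 95% intervals of neighbouring classes overlapped. With 3′ UTR length and GC taken out, the medians were -0.196, -0.151, -0.110 and -0.017 at 72 h. At 48 h they were -0.142, -0.084, -0.051 and -0.010. At both times the adjusted intervals of the 8-base and first 7-base class overlapped. From 48 to 72 h the 8-base and 7-base medians were -0.22 and -0.24 (-0.05 and -0.04 after scaling), so the order of site strength stays open. The z of ACTAGAT was weaker in coding sequence (-4.98) and not below 0 in 5′ UTRs (39 genes). Of 328 genes lower by 2-fold or more, 22 held the 8-base site (odds ratio 4.05, Fisher's exact p = 2.39e-07). COX7C, DDX21 and AGO1 were among them. After scaling 10 of 160 held it (odds ratio 3.59, Fisher's exact p = 0.000887). No match of 6 bases or longer was held by 68.6% of the 328, against 76.27% of all genes with a 3′ UTR. TRIB3, CST7 and YES1 held none of 7. Matches to this site in 3′ UTRs thus do not account for most of the large falls. Matches to any other seed of the siRNA, whose sequence is not given, were not counted.

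The higher values at 24 h of genes with certain words, relative to other genes, may in part be release from seed matches of the negative-control siRNA. As deposited the median of the genes below did not rise but fell less, and it lay above 0 only after scaling. The highest words at 24 h, TTACAAA (z 9.87) and ATTACAA (z 9.39), overlap into 1 8-base site, whose 715 genes had a median of -0.046, against -0.093 without a site (0.044 and -0.007 after scaling). Over 101 other arrangements of the bases of TTACAAA sharing no 6 bases with the site the highest z was 2.63, which argues against base composition; TACAAAT, which shares 6, had 5.63, and 1.96 in genes without either word. Against 0 h the z of TTACAAA and ATTACAA declined to 5.93 and 6.42 at 48 h and 5.40 and 2.85 at 72 h, the last within the limit, with 8-base and no-site medians of 0.065 and -0.036 at 48 h and -0.100 and -0.217 at 72 h, and from 24 to 72 h, without the control libraries, it was 2.16 and -0.28, within the limit; the medians were then -0.054 and -0.125, apart, but -0.020 (bootstrap 95% interval -0.057 to 0.003) and -0.028 (-0.036 to -0.016) with 3′ UTR length and GC taken out, against 0.047 and -0.012 at 24 h. Both words also lie in TCF7L2, as 30.44% of all words do. Neither the sequence of the control siRNA nor a control at later times was used here, so time since transfection stays open. The control was labelled 0 h, and a harvest right at transfection would have left its siRNA no time to lower any gene.

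Genes with words of the miR-17/92 families had z values above 0 at 72 h, none past the limit of 4.667 against 0 h (highest 4.52), though GTGCAAT and CACTTTA passed it from 24 to 72 h (5.27 and 4.88) and 48 to 72 h (4.97 and 5.23), and lower activity of this MYC-regulated cluster is a candidate explanation. Over its 4 families the median z was 2.77 against 0.40 for 16 others (exact permutation p = 0.0111, two-sided), but words of these families had been noticed first, so the test was partly circular. A second test, written after the first was seen and limited to miR-18 and miR-19, gave a difference of 1.47 (exact permutation p = 0.248, two-sided) and leaves it open, since miR-23 (mean z 2.95) and miR-200b (2.48), outside the cluster, lay above miR-18 (1.57) and miR-19 (2.17). The median of the other families, 0.4, lay within the -0.733 to 0.54 of random word sets, so competition of the siRNA with all microRNAs stays open.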
